A study of Mus musculus with 10 samples.

How the data were processed

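The series measured gene expression in 10 subcutaneous 4T1 mammary tumors grown in syngeneic BALB/c mice. 4T1 is a transplantable mouse mammary carcinoma line. The labels assign 5 tumors to a control shRNA and 5 to an shRNA against Cebpb, the gene for the transcription factor C/EBP-beta, and describe each as a separate tumor. All were removed 2 weeks after implantation. Total RNA from each tumor was treated with DNase on the column and hybridised with 1 dye to 1 NimbleGen mouse array, per the labels' protocols.

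The authors deposited gene-level intensities on a linear scale, 1 value per sequence and array. RMA is named in the submitters' processing notes, without a version. RMA corrects the background, normalizes arrays together and summarises the probes of a sequence. Which arrays were normalized together is not given in the sources used here, although the intensities show that the arrays do not all share 1 distribution. Per the file headers, each array has 44170 gene sequences and 1 random-sequence control. The labels describe 14 probe pairs of 24 nucleotides per gene in 3 copies, while the probe-pair column lists 3 pairs for 44155 sequences, 2 for 9 and 1 for 6. What that column counts was not settled. A further deposited column named as a standard error was not used in any test, since its definition is not stated. The deposited series table held the same intensities, with a largest difference of 0 from the array files. Array medians of that table therefore equal those of the files, its values are linear and uncentred, and its step from probe to gene is the same.

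Deposited intensities were converted to log2 with no further normalization and no pseudocount, as fixed before the data were examined. Sequences, called features here, were named through the gene identifiers in the files. Of these identifiers, 39057 matched a RefSeq gene table of assembly GRCm38.p6, used for symbols only, and 2829 features kept the name in the file. In all, 41886 features had a symbol, 2284 had none, and 24171 genes were represented. Gene names follow the array's design and can be old. Coordinates are those of the files, on build mm9. Cebpb itself was not analysed here, because no feature used here carried that name or gene identifier, so the knockdown was not checked.

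Features were compared between the groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05), with 5 arrays per group, no covariate and no replicate block. A second count also required an absolute log2 fold change of at least 1. Fold changes are Cebpb shRNA minus control shRNA, and p-values per feature concern the spread between separate tumors. Gene lists were compared with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 26 lists. Camera compares the members of a list with other genes. At this preset correlation its p-values rest mainly on the spread across genes and do not measure the spread between tumors. The lists held 473 entries, or 471 distinct genes, and were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Each gene was represented by its feature with the highest mean. A list needed 5 measured members. Camera with an estimated correlation and fry were run beside it. Fry tests whether the members of a list move on balance in 1 direction and does not compare them with other genes.

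The rule for named genes took up to 12 genes per direction with the largest change among those with an adjusted p under 0.05 and fully separated groups, leaving out unnamed features and symbols of predicted genes. Where fewer than 6 passed, the genes with the smallest p filled the number up to 6. For each list called by camera the 4 members with the smallest p were taken, and for each other list 2. This gave 91 genes, of which 36 had several features. In 33 of these, all features of the gene had the same sign of fold change. In H2-DMa, Ttn and Mmp12 at least 1 feature had the opposite sign. Genes named outside this rule are said to be so, and 1 gene that the rule names is not reported.

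The median residual SD, 1.5 log2 units over 10 arrays and 0.30 over the 8 arrays with the higher lowest intensity, sets the precision. Signal over background was judged against 989 features of olfactory and vomeronasal receptor genes, which are hardly transcribed outside sensory tissue. That reference, and a division of the arrays by their lowest intensity under or over 50, were chosen after the data were seen. The tests were tried on simulated data drawn from the real means and residual SDs. For 10 arrays and 44170 features, the test recovered 0% of 100 features changed by a log2 of 1 and 0% of 100 changed by a log2 of 2. For the 8 arrays with the higher lowest intensity, 30% and 80% were recovered, with 7 false calls. Camera recovered a shift of 1 in the macrophage list over 24171 genes in each simulation, with 0 false calls, but the simulated genes varied independently.

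Alternatives fixed beforehand were median centring, quantile normalization, the series table, a trended robust prior, array weights, replicate number as a block, leaving out each tumor, dropping the dimmer 50% of features, other thresholds, mean values per gene and an estimated correlation. Fits with the array set as a block and within the 8 arrays were added after seeing the data. Python 3.11.15 with matplotlib 3.10.9 drew the figures.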

Results

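Expression was measured in 5 control shRNA tumors and 5 Cebpb shRNA tumors, each a separate 4T1 mammary tumor removed 2 weeks after implantation and hybridised to its own array. The comparison asks which transcripts differ in tumors that carry an shRNA against Cebpb, a transcription factor gene of mammary and myeloid cells. The arrays fell into 2 sets that did not follow the groups. Control tumor 5 and Cebpb shRNA tumor 4 had a lowest intensity of 3.61 and 3.67, a median of 140 and 158, and an interquartile range of 5.97 and 5.93 log2 units. The other 8 arrays, called high-floor arrays here, had a lowest intensity of 120 to 125, a median of 668 to 719 and an interquartile range of 2.05 to 2.24 log2 units.

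Genes that tumors should not transcribe were bright on the high-floor arrays. The 989 features of olfactory and vomeronasal receptor genes, which serve smell and pheromone sensing, lay 2.60 and 2.41 log2 units below the array median on control tumor 5 and Cebpb shRNA tumor 4. On 7 high-floor arrays their median lay 0.33 to 0.58 log2 units above the array median, and on control tumor 1 it lay at -0.50. Features above the 95th percentile of the receptors made up 46.8% and 43.2% of all features on the low-floor pair. That share was 12.3% on control tumor 1 and 2.61% to 4.11% on the remaining 7. Top2a, a topoisomerase of dividing cells, stood at a log2 intensity of 13.07 and 13.05 on the low-floor pair and at 13.15 on control tumor 1, but at 8.37 to 9.47 on the other 7 arrays. Top2a was chosen after its values were seen. The median Spearman correlation across features was 0.962 within the high-floor arrays and 0.235 between the sets, and it was 0.881 for the low-floor pair. The first principal component held 91.4% of the variance and separated the sets.

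**Figure D1:**
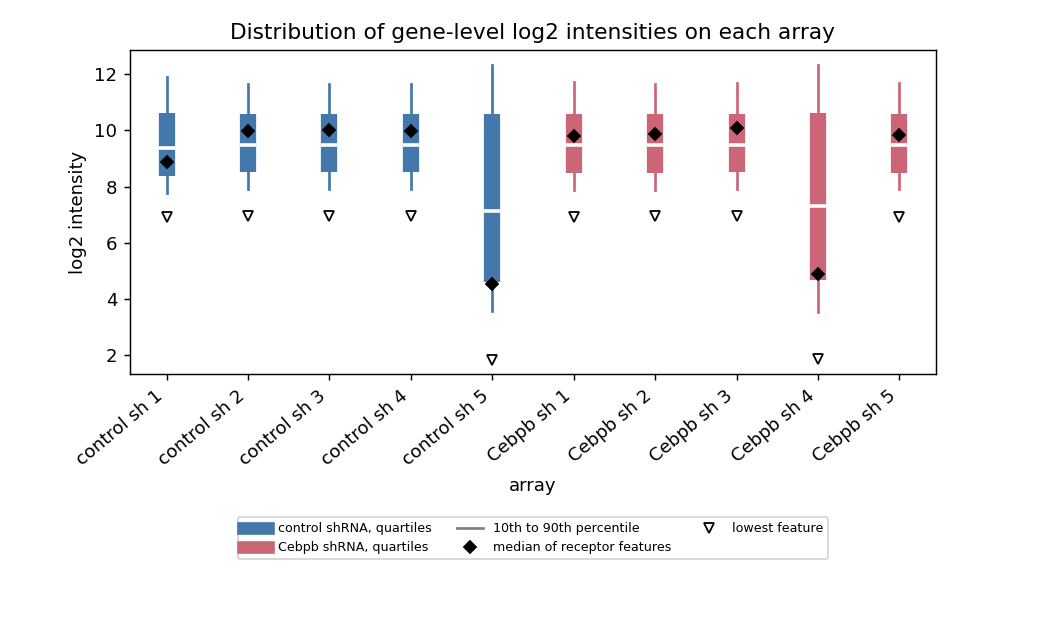
Log2 intensity (y axis) of the 44170 features on each array (x axis), with quartile bars, white medians, lines that leave out the extreme 10% on each side, diamonds for the median of 989 receptor features and triangles for the lowest feature. The receptors lie 2.60 and 2.41 log2 units below the median on control tumor 5 and Cebpb shRNA tumor 4, and above it on 7 other arrays.

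**Figure D2:**
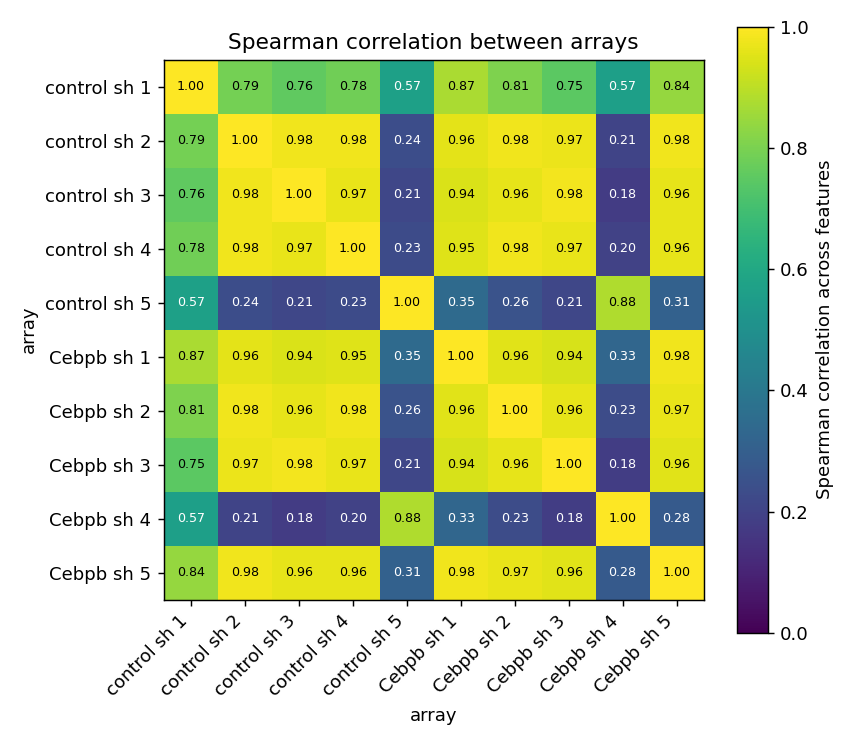
Spearman correlation across features for each pair of arrays, with arrays on both axes and the colour scale running from 0 to 1. Control tumor 5 and Cebpb shRNA tumor 4 correlate at 0.88 with each other and at no more than 0.57 with any other array.

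The shRNA target itself was not analysed here. The C/EBP family list had 5 measured members with a median log2 fold change of -0.04, and 2 of the 5 were higher with the Cebpb shRNA (camera adjusted p = 0.955). That median went to -0.64 without Cebpb shRNA tumor 4 (camera adjusted p = 0.052) and to 0.20 without control tumor 5 (camera adjusted p = 0.124). Cebpa, a relative of Cebpb that drives adipocyte and granulocyte differentiation, had a log2 intensity of 10.21 ± 0.53 (SD, n = 5) in control tumors and 10.46 ± 0.23 (SD, n = 5) in Cebpb shRNA tumors. Ddit3, the stress-response member also called CHOP, had 10.35 ± 1.60 and 10.04 ± 1.53 (SD, n = 5 each). Neither gene passed the limma test, each with an adjusted p of 0.999997.

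No single gene passed the test between the groups. Of 44170 features, limma called 0 at an adjusted p under 0.05, 0 of them at least 2-fold, and 0 reached an unadjusted p under 0.05. The smallest p was 0.083, with a smallest adjusted p of 0.999997. The 5 values of each group did not overlap for 13 features, or 0.029%, against 0.794% expected by chance. The median residual SD was 1.5 log2 units over the 10 arrays and 0.30 over the 8 high-floor arrays.

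The genes with the smallest p, none of which passed, were higher with the Cebpb shRNA for Mylk, Cd36, Cd3e, Nppb, Prkch and Lilr4b. Mylk, the myosin light chain kinase of contractile cells (chromosome 16, 34921598 to 34930036), had 9.63 ± 0.90 (SD, n = 5) in control tumors and 10.59 ± 0.56 (SD, n = 5) in Cebpb shRNA tumors. Cd36, a fatty acid transporter and scavenger receptor (chromosome 5, 17287833 to 17355573), had 6.67 ± 2.02 and 8.47 ± 1.20 (SD, n = 5 each). Cd3e, a chain of the T cell receptor complex, had means of 8.92 and 10.33, with SDs of 1.52 and 1.0 (n = 5 each). The lower genes included Nbn, Dennd5b, Zc3hc1, Cdkn2a and Galnt13. Nbn, which acts in DNA double-strand break repair (chromosome 4, 15885114 to 15919736), had 9.55 ± 0.67 in control tumors and 8.76 ± 0.47 in Cebpb shRNA tumors. Cdkn2a, which encodes the cell cycle inhibitors p16 and p19 (chromosome 4, 88920444 to 88940443), had 8.80 ± 1.71 and 7.04 ± 1.96. Log2 fold changes of these genes ran from -1.92 with an SE of 1.18 for Galnt13 to 1.80 with an SE of 0.98 for Cd36. In the low-floor pair alone, Cd36 differed by 7.31 log2 units and Galnt13 by -8.51, each against a value below the receptor median of its array and so against background, while over the 8 high-floor arrays the differences of the group means were 0.42 and -0.27.

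**Figure D3:**
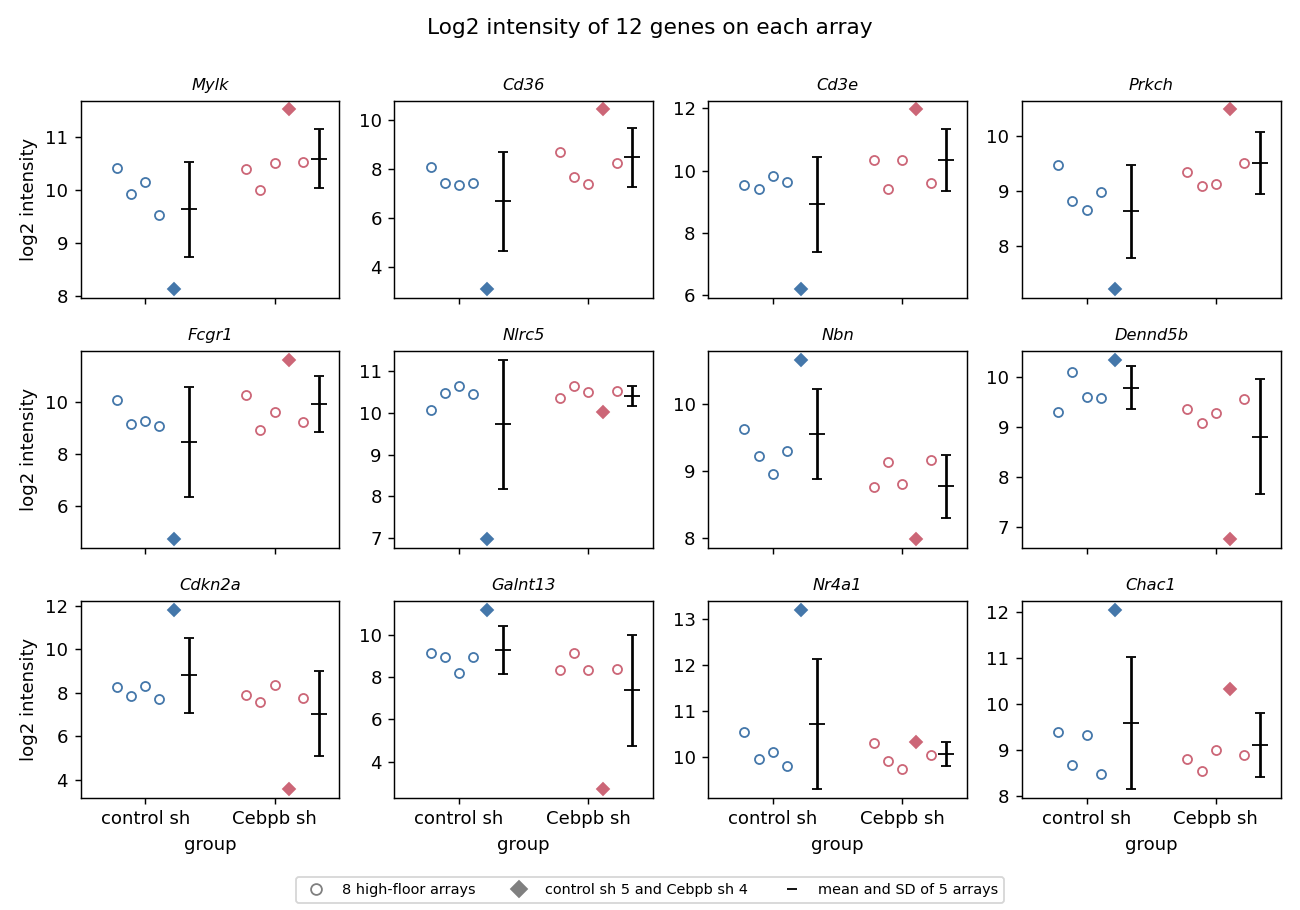
Log2 intensity (y axis) of 12 genes in control shRNA (blue) and Cebpb shRNA (red) tumors, with open circles for the 8 high-floor arrays, filled diamonds for control tumor 5 and Cebpb shRNA tumor 4, and black bars for the mean and SD of 5 arrays. For Cd36 the diamonds stand at 3.10 and 10.41, outside the range of 7.34 to 8.67 of the circles.

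Genes of antigen presentation were higher as lists with the Cebpb shRNA over the 10 arrays. Of 15 members of the MHC class II list, which presents peptides to helper T cells, 13 were higher, with a median log2 fold change of 0.94 (camera adjusted p = 4.5e-13). The call was lost with an estimated correlation, at an adjusted p = 0.139. H2-Aa had 9.14 ± 2.86 (SD, n = 5) in control tumors and 11.29 ± 2.12 (SD, n = 5) in Cebpb shRNA tumors, and H2-Ea had 10.23 ± 3.60 and 12.45 ± 1.62. The MHC class I list had 16 of 19 members higher at a median of 0.41 (adjusted p = 1.8e-07, and adjusted p = 0.297 with an estimated correlation). Its immunoproteasome member Psmb9 had 11.24 ± 1.66 and 12.32 ± 1.22. The interferon response list had 24 of 25 members higher at a median of 0.86 (adjusted p = 1.4e-15, and adjusted p = 0.191 with an estimated correlation). Cxcl9, a chemokine induced by interferon gamma, had 8.78 ± 2.89 and 10.62 ± 2.12. Without Cebpb shRNA tumor 4 the calls of these 3 lists ended, with medians of 1.06, 0.35 and 0.51 (adjusted p = 0.300, 0.501 and 0.640). Against other genes, camera's direction there turned to lower for the MHC class I and interferon lists, although their medians stayed positive. Without control tumor 5 they stayed called higher, with medians of 0.27, 0.32 and 0.34.

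Leukocyte and endothelial markers followed the same direction. All 19 measured macrophage and monocyte markers were higher, at a median of 0.91 (adjusted p = 6.8e-22, and adjusted p = 0.139 with an estimated correlation). Among them, the lysozyme gene Lyz2 had 9.83 ± 2.78 in control tumors and 12.19 ± 2.24 in Cebpb shRNA tumors, and the complement gene C1qc had 9.70 ± 3.41 and 12.25 ± 1.87 (SD, n = 5 each). T cell markers were higher in 19 of 21 members at a median of 0.53 (adjusted p = 2.2e-09, and 0.382 as the adjusted p with an estimated correlation). NK and cytotoxic cell markers were higher in 13 of 13 at 0.97 (adjusted p = 5.5e-12, and adjusted p = 0.248 with an estimated correlation). Gzma, a granule protease of cytotoxic cells, had 7.69 ± 2.77 and 9.29 ± 1.35. B cell and plasma cell markers were higher in 10 of 14 at 0.38 (adjusted p = 0.00075, and adjusted p = 0.499 with an estimated correlation). Neutrophil and granulocyte markers were higher in 15 of 19 at 0.57 (adjusted p = 3.9e-07, and adjusted p = 0.422 with an estimated correlation). Dendritic cell markers were higher in 10 of 12 at 0.71 (adjusted p = 4.5e-05, and adjusted p = 0.297 with an estimated correlation). Endothelial markers were higher in 14 of 14 at 0.76 (adjusted p = 2.9e-09, and adjusted p = 0.297 with an estimated correlation), with Emcn, an endothelial sialomucin, at 8.83 ± 2.91 and 10.22 ± 0.70. Without control tumor 5 the calls of the T cell, NK cell, B cell, neutrophil, dendritic cell and endothelial lists ended and their medians turned to -0.45, -0.17, -0.70, -0.43, -0.11 and -0.25. Without Cebpb shRNA tumor 4 their medians were 1.04, 1.01, 0.99, 1.18, 0.93 and 1.02, with the dendritic cell (adjusted p = 0.347) and endothelial (adjusted p = 0.052) calls ended and the others kept. Lists of other tissues moved alike in that fit, to 1.07 for adipocyte, 1.11 for skeletal muscle, 1.07 for keratinocyte, 1.02 for luminal and 1.08 for milk genes. These moves are thus not particular to leukocyte or endothelial markers. The macrophage list had a median of 0.92, near the full value, but no call without Cebpb shRNA tumor 4 (adjusted p = 0.071), and a median of 0.35 with a call without control tumor 5 (adjusted p = 4.9e-06).

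Shifts were also called in 5 further lists. Inflammatory cytokines and acute-phase genes were higher in 18 of 26 members at a median of 0.16 (adjusted p = 0.011, and adjusted p = 0.456 with an estimated correlation). Within this list the neutrophil chemokine Cxcl1 went the other way, with 10.24 ± 0.63 and 9.54 ± 0.67. Matrix proteases and inhibitors were higher in 12 of 19 at 0.07 (adjusted p = 0.0076, and adjusted p = 0.297 with an estimated correlation). Red blood cell genes were called higher at an adjusted p = 0.0060, although only 3 of 7 were higher and their median was -0.02 beside a mean of 0.44. With an estimated correlation their adjusted p was 0.422. Proliferation genes were lower, with 4 of 26 members higher at a median of -0.26 (adjusted p = 0.0049, and adjusted p = 0.674 with an estimated correlation). Ttk, a spindle checkpoint kinase, had 10.29 ± 1.01 in control tumors and 9.59 ± 0.98 in Cebpb shRNA tumors. The proliferation list was called in the opposite direction without control tumor 5 (median 0.26, adjusted p = 1.6e-05) and with array weights (median 0.30, adjusted p = 1.6e-05). The list of RNA damage and early response genes was lower, with 1 of 15 higher at -0.39 (adjusted p = 3.8e-07, and adjusted p = 0.139 with an estimated correlation). Its heat shock member Hspa1b had 9.66 ± 1.22 and 8.61 ± 0.90, and the immediate early gene Nr4a1 had 10.73 ± 1.41 and 10.07 ± 0.25. Without control tumor 5 the early response call ended (adjusted p = 0.254), as did those of inflammatory genes (median -0.19, adjusted p = 0.158) and red blood cell genes (median -0.81, adjusted p = 0.769). Without Cebpb shRNA tumor 4 the calls of inflammatory (median 0.68, adjusted p = 0.699), red blood cell (median 1.17, adjusted p = 0.105) and matrix protease genes (median 0.03, adjusted p = 0.174) ended.

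Lists of tumor and tissue identity were not called over the 10 arrays. Medians were 0.13 for adipocyte markers (adjusted p = 0.066), 0.00 for skeletal muscle markers (adjusted p = 0.470), 0.08 for keratinocyte and skin markers (adjusted p = 0.990) and 0.17 for milk and mammary differentiation genes (adjusted p = 0.078). Luminal and simple epithelial genes had -0.08 (adjusted p = 0.955), fibroblast and extracellular matrix genes -0.08 (adjusted p = 0.798) and mesenchymal transition genes -0.10 (adjusted p = 0.117). Leaving out 1 tumor moved several of these lists. Without control tumor 5 or Cebpb shRNA tumor 4, 1 low-floor array stays in 1 group only, so the difference between the array sets enters the fold changes. Median log2 intensities of skeletal muscle markers were 5.29 and 4.84 on these 2 arrays, against 9.37 to 10.47 on the high-floor arrays. Fibroblast genes lay the other way, at 12.27 and 11.92 against 9.41 to 11.22. Skeletal muscle markers went to 1.11 without Cebpb shRNA tumor 4 (adjusted p = 0.0020) and -0.85 without control tumor 5 (adjusted p = 0.124). Without control tumor 5 luminal genes were called lower at -1.05 (adjusted p = 0.028) and keratinocyte markers at -1.04 (adjusted p = 0.025). They moved as far the other way without Cebpb shRNA tumor 4, to 1.02 (adjusted p = 0.0510) and 1.07 (adjusted p = 0.0504), just short of a call. Fibroblast genes were called higher without control tumor 5 (0.35, adjusted p = 4.7e-06) and lower without Cebpb shRNA tumor 4 (-0.35, adjusted p = 0.0010). Hypoxia and glycolysis genes had 0.07 (adjusted p = 0.238), unfolded protein and amino acid stress response genes -0.07 (adjusted p = 0.350), and apoptosis and senescence genes 0.01 (adjusted p = 0.550). These 3 lists and the mesenchymal list were each called higher without control tumor 5 (0.25, 0.24, 0.30 and 0.16, adjusted p = 4.1e-05, 3.2e-05, 0.00029 and 6.5e-05) and lower without Cebpb shRNA tumor 4 (-0.27, -0.69, -0.30 and -0.36, adjusted p = 0.0013, 4.6e-06, 0.00043 and 5.7e-06). The median and camera's direction differed in sign for 4 of the 26 lists, namely the C/EBP family, keratinocyte, apoptosis and red blood cell lists. Fry called 0 lists, with a smallest adjusted p of 0.9998 for 1 direction and 0.868 for changes either way. No list member passed the test over all genes or adjusted over the list alone, and 0 reached an unadjusted p under 0.05.

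The shifts of the macrophage, MHC class II, interferon, NK cell and endothelial lists were far larger in the low-floor pair than over the other arrays. In the low-floor pair, 1 array per group and thus without a test, Cebpb shRNA tumor 4 exceeded control tumor 5 by a median of 5.05 log2 units for macrophage markers, 4.57 for MHC class II, 4.24 for interferon response, 4.17 for NK cell and 4.14 for endothelial genes. On control tumor 5 most members of the macrophage, MHC class II, NK cell and endothelial lists did not exceed the receptor level. These differences are thus largely against values not clearly above background, and not exact. Over the 8 high-floor arrays these medians were 0.07, 0.13, -0.06, 0.05 and -0.02, and none of the 13 lists called higher over 10 arrays was called higher. There, camera called 3 lists: adipocyte markers at 0.21 (adjusted p = 0.0087) and skeletal muscle markers at 0.23 (adjusted p = 0.0059) were higher, and proliferation genes at -0.22 (adjusted p = 0.015) were lower. Leaving out control tumor 1 as well turned the proliferation call round (median 0.24, adjusted p = 1.0e-05) and ended the adipocyte and skeletal muscle calls. Over these 7 arrays, 12 lists were called higher, among them 6 of the 13: MHC class II at 0.53, MHC class I at 0.73, macrophage at 0.44, interferon response at 0.31, endothelial at 0.11 and matrix protease genes at 0.10. Also called higher were fibroblast at 0.20, mesenchymal at 0.14, proliferation at 0.24, hypoxia at 0.28, unfolded protein at 0.18 and apoptosis genes at 0.17. Control tumor 1 had 10 of 15 MHC class II and 9 of 19 macrophage members above the receptor level. Cebpb shRNA tumor 1, with 6 and 5, was kept. Leaving out control tumor 1 alone thus favours higher values in these lists. With the array set as a block, 12 of the 15 lists called over 10 arrays were called in the same direction. Each group holds 1 low-floor array, so this block leaves every fold change as it was, and the shared direction decides nothing.

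**Figure D4:**
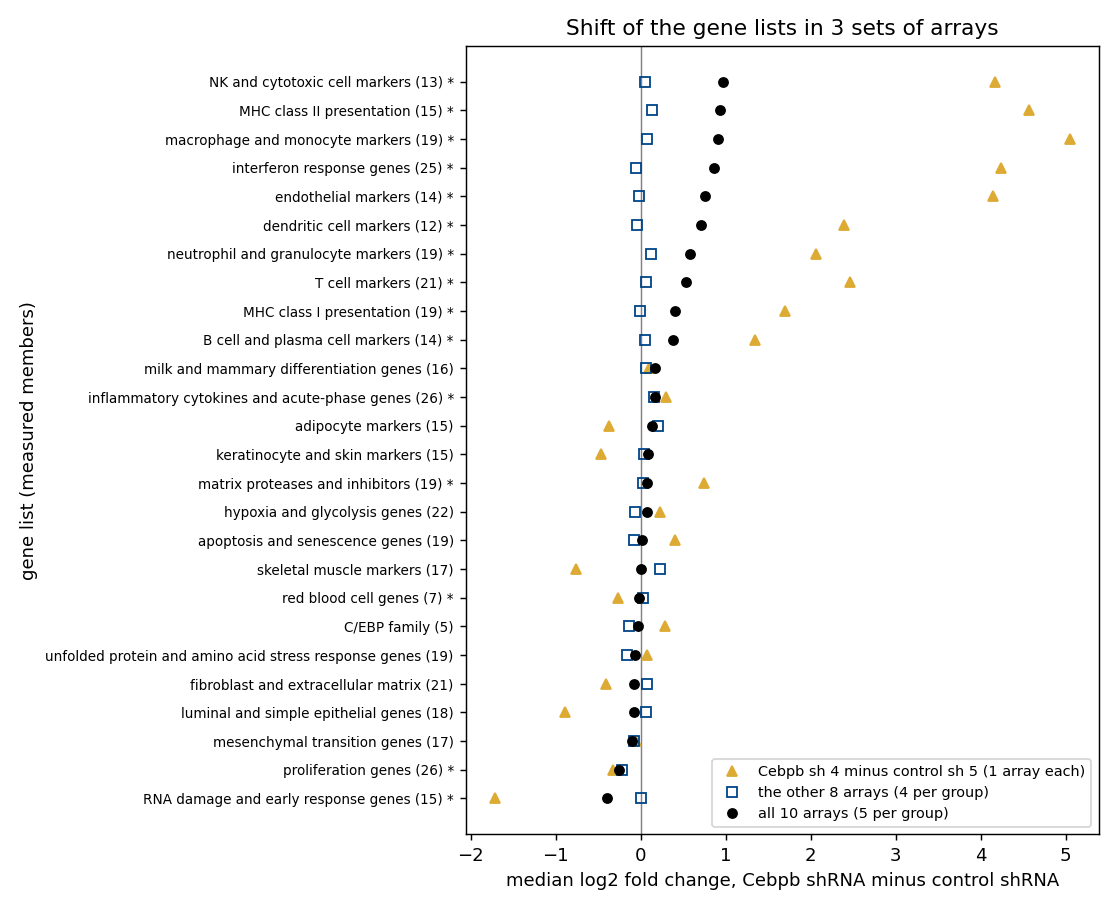
Median log2 fold change (x axis, Cebpb shRNA minus control shRNA) of the measured members of 26 gene lists (y axis, number of members in parentheses, asterisk for a camera adjusted p under 0.05 over 10 arrays), for all 10 arrays, for the 8 high-floor arrays and for Cebpb shRNA tumor 4 minus control tumor 5. The macrophage list lies at 0.91, 0.07 and 5.05 in these 3 sets.

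Marker levels were also set against the receptor features within single arrays. On control tumor 5, 4 of 19 macrophage, 0 of 14 endothelial, 0 of 13 NK cell and 2 of 21 T cell markers lay above the 95th percentile of the receptor features. On Cebpb shRNA tumor 4 these counts were 16, 10, 7 and 11. Of all features, 46.8% on control tumor 5 and 43.2% on Cebpb shRNA tumor 4 lay above that level. The NK cell and T cell counts on Cebpb shRNA tumor 4 thus stood near the share of all features. Mesenchymal transition genes were above that level in 17 of 17 members on control tumor 5 and 16 of 17 on Cebpb shRNA tumor 4, and proliferation genes in 25 and 24 of 26. Luminal and simple epithelial genes were above it in 3 and 2 of 18. Control tumor 1, a high-floor array, had a log2 intensity of 14.62 for Lyz2, 14.45 for C1qc and 14.73 for H2-Ea. Cebpb shRNA tumor 4 had values near these, 14.54, 14.24 and 14.26, although the 2 arrays are not on a shared scale. The high-floor array of Cebpb shRNA tumor 1 was close, at 14.13, 13.51 and 14.03. Lyz2 stood at 8.69 to 9.51 in control tumors 2 to 4 and at 11.07, 9.09 and 12.10 in Cebpb shRNA tumors 2, 3 and 5.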

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

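All tests weighed here were chosen after the result was seen, except the count of splits for the gene lists, which was written before. Within each group of 5 tumors, 246 array measures, list medians and named genes were tested for 1 tumor far from the others, by the gap to its nearest neighbour over the range of the group (limit 0.71). List medians and genes entered as log2 intensities, although the floors of the arrays differ. A dim list or gene can thus be lowest on a low-floor array for that reason alone. The rule picked 118, where chance would pick about 12. All but 4 concern control tumor 5 or Cebpb shRNA tumor 4, and the 4 concern control tumor 1 (3) and Cebpb shRNA tumor 3 (1).

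Control tumor 5 was lowest among control tumors in lowest intensity (0.97), median intensity (0.91) and the random-sequence control (0.85), and highest in interquartile range (0.95) and in the share of features above the receptor level (0.78). It was lowest for the list medians of MHC class II (0.77), T cell (0.89), B cell (0.92), NK cell (0.88), macrophage (0.72), neutrophil (0.85), dendritic cell (0.89), endothelial (0.87), adipocyte (0.85), skeletal muscle (0.82), keratinocyte (0.95), luminal (0.85), milk (0.85), inflammatory (0.87) and red blood cell genes (0.85). It was highest for the RNA damage and early response list (0.74). Set against the receptor median of each array, only the red blood cell list among these lowest lists stayed lowest, at 0.64 log2 units.

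Among leukocyte genes, control tumor 5 was lowest for S100a8 (0.96), Ighm and Klrd1 (0.92), Nkg7 (0.91), Cd3d and Clec9a (0.90), Cd3g and Cd2 (0.89), Cd3e and Cd22 (0.88), Cd79b and Cd86 (0.87), Cd83 (0.86), Cd80 and Nlrc5 (0.85), Tnfrsf17 (0.84), Fpr2 (0.83), Lilr4b, Ccl3 and Tnf (0.82), Fcgr1 (0.81), Lcn2 (0.80), Fpr1 (0.76) and Gzma (0.74). Among vessel, tissue and matrix genes it was lowest for Adm (0.93), Mmp12 (0.92), Tnni2 and Slc4a1 (0.89), Krt18 (0.88), Nppb (0.87), Lum and Ttn (0.86), Cd36 and Eng (0.85), Alas2 (0.82), Emcn (0.81), and Mmp2 and Mmp13 (0.76). It was highest for the contractile gene Tagln (0.96), the collagen crosslinking gene Lox (0.87), Cdkn2a (0.86), Hspa1b (0.85), Nr4a1 (0.78) and the stress gene Chac1 (0.74).

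Cebpb shRNA tumor 4 was lowest in its group in median intensity (0.98), lowest intensity (0.96), the random-sequence control (0.92) and receptor level against the array median (0.91), and highest in interquartile range (0.99) and in the share of features above the receptor level (0.96). It was lowest for the medians of the B cell and milk lists (0.98), red blood cell list (0.97), skeletal muscle and luminal lists (0.92), keratinocyte list (0.91), neutrophil list (0.89), adipocyte list (0.88), T cell list (0.87), dendritic cell list (0.81) and endothelial list (0.79). It was highest for the C/EBP family (0.95), proliferation (0.83) and unfolded protein (0.80) lists. Against the receptor median of each array, it was instead highest for the B cell, neutrophil, adipocyte, T cell, dendritic cell and endothelial lists. These lay 0.37, 1.88, 2.03, 3.39, 4.01 and 4.37 log2 units above that median. The milk, red blood cell, skeletal muscle, luminal and keratinocyte lists stayed lowest.

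Among genes, Cebpb shRNA tumor 4 was highest for Ighm (0.95), Flt1 (0.91), Ankrd37 (0.89), Gzma (0.85), Klrd1 (0.82), Mmp13 (0.81), Lilr4b (0.79), Cd80 and Tyms (0.78), Ttk (0.77), Chac1 (0.75), Esam (0.73), Ddit3 (0.72) and Csn3 (0.71). It was lowest for Slc4a1 (0.97), Atf3 (0.96), Krtdap (0.95), Cdkn2b (0.94), Krt19 (0.93), Ttn and Hspa1b (0.90), Fbln1 (0.89), Galnt13 (0.88), Dennd5b and Cdkn2a (0.83), Tnni2 (0.73) and Cxcl1 (0.72). Control tumor 1 was highest for the fatty acid carrier Fabp4 (0.90), Adam8 (0.80) and Lyz2 (0.71), and Cebpb shRNA tumor 3 for the iron-binding gene Lcn2 (0.84).

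The first pattern is that 2 arrays stand apart from 8. The shRNA group does not explain it, since control tumor 5 correlated at 0.881 with Cebpb shRNA tumor 4 and at most at 0.570 with another control. A separate rescaling as the whole cause is argued against, because it keeps the order of features, while the median rank correlation between the sets was 0.235. Separate RMA runs also correct and summarise probes, which need not keep that order and was not tested. Genomic DNA of female cells as a main source of signal on the 8 arrays stays open, as receptor genes lay above the array median on 7 of the 8 arrays, although the labels report a DNase step and other unspecific signal was not tested. Chromosome Y features decide nothing, since the share within 1 log2 unit of the lowest feature was 61.1% against 10.7% of all features on the 8 arrays, and 37.0% against 2.08% and 2.36% on the low-floor pair.

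The second pattern is the higher leukocyte, interferon and endothelial lists with the Cebpb shRNA. Whether the 2 low-floor arrays alone carry these calls and whether the shRNA acts in all tumors could not be told apart, since 0 of the 13 lists called higher were called higher over the 8 high-floor arrays and 6 over 7 of them without control tumor 1. The fit over 7 arrays cannot decide this. Control tumor 1, left out of it, had 14.3% of leukocyte markers above the receptor level, and Cebpb shRNA tumor 1, with 5.10%, was kept. These values are near the shares of all features on the 2 arrays, 12.3% and 4.11%. The remaining high-floor arrays had 0% to 1.02% of leukocyte markers above that level, beside 2.61% to 3.44% of all features. Little leukocyte RNA in control tumor 5 fits, with 10.2% of leukocyte markers above the receptor level against 53.1% on Cebpb shRNA tumor 4. The shares of all features above it were 46.8% and 43.2%. Chance cannot be excluded, because 59 of 100 splits of the tumors, the real split included, gave at least its 15 lists, up to 19 in another.

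The third pattern is that control tumor 1 lies between the sets. Its departure from the other high-floor arrays correlated at 0.566 with the low-floor mean, against at most 0.265 for any other of the 8, which fits more tumor RNA signal on that array. The median for the other high-floor controls was -0.438. They were set against a mean that includes control tumor 1, which pushes them the other way, so this value does not decide on the shRNA group. Across features, control tumor 1 correlated at 0.756 to 0.792 with control tumors 2 to 4 and at 0.875 with Cebpb shRNA tumor 1.

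For the counts of features, and of features changed at least 2-fold, the real count of 0 is reached by every split by construction (100 of 100, highest other 0), so these splits decide nothing. Splits with the low-floor arrays in opposite groups, as in the real split, called a median of 16 lists. Splits with both in the same group and control tumor 1 beside them had 1053 to 7724 features at an unadjusted p under 0.05. With control tumor 1 in the other group the count was at most 174, below the 426 reached with the pair apart. The largest counts thus follow the low-floor pair together with control tumor 1.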

How the results depend on the processing

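The fits by array set were chosen after seeing the data. No feature passed under any setting, and the Cebpb level gave no value. Between 11 and 18 lists were called under the planned settings, 12 to 18 when each tumor was left out, except 0 with an estimated correlation. Without control tumor 5, 13 lists were called but only 5 of the 15 in the same direction, and without Cebpb shRNA tumor 4, 12 and 6. With the array set as a block 12 lists were called, all in the same direction, which decides nothing because this block leaves every fold change as it was. Over the 8 high-floor arrays 3 were called, and over 7, without control tumor 1, 12 (6 of the 15 in the same direction, 1 opposite). No named gene passed under any setting, with the sign of its fold change kept in 1692 values and turned in 98. Of list values, 384 were the same, 64 weaker, 33 stronger, 50 moved and 39 reversed. Signal over background limits the 8 arrays, as only 2.61% to 12.3% of their features exceeded the receptor level.

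Reversals follow camera's direction, so that some medians keep their sign. Fits without 1 low-floor array keep the other in 1 group only, so the difference between the array sets enters their fold changes. Causes of the reversals were not tested. With array weights, which gave control tumor 5 and Cebpb shRNA tumor 4 weights of 0.0106 and 0.0112, reversed medians were -0.0642 for T cell, -0.0471 for B cell, -0.0851 for neutrophil, -0.17 for dendritic cell, 0.27 for fibroblast, 0.15 for mesenchymal, 0.30 for proliferation, 0.20 for unfolded protein, 0.19 for apoptosis and 0.0868 for early response genes. Over the 8 high-floor arrays they were -0.00900 for MHC class I, 0.0482 for B cell, -0.0446 for dendritic cell, -0.0174 for endothelial, -0.0578 for interferon and 0.0212 for matrix protease genes. Over 7, without control tumor 1, they were -0.0705 for T cell, -0.0415 for B cell, -0.0447 for neutrophil, -0.12 for dendritic cell, 0.20 for fibroblast, 0.14 for mesenchymal, 0.24 for proliferation, 0.18 for unfolded protein, 0.17 for apoptosis and 0.0641 for early response genes. Leaving out each tumor, lists with a reversal ranged from 0.20 to 0.88 for MHC class I, -0.70 to 0.99 for B cell, -0.35 to 0.35 for fibroblast, -0.25 to 1.14 for endothelial, -0.36 to 0.16 for mesenchymal, -0.72 to 0.26 for proliferation, 0.34 to 1.12 for interferon, -0.27 to 0.31 for hypoxia, -0.69 to 0.24 for unfolded protein, -0.0652 to 0.43 for matrix protease, -0.30 to 0.30 for apoptosis and -0.58 to -0.0336 for early response genes.

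Correlations between tumors of the same replicate number were 0.204, 0.859, 0.905, -0.881 and -0.832. The first 3 pairs correlated best with their own number, a hint from the data, and each of the last 2 holds a low-floor array. Values were taken against group means that include the low-floor array, so the signs largely follow the array sets. Control tumor 4 correlated at 0.868 with Cebpb shRNA tumor 2, above the second pair, so these correlations do not settle the pairing. Since not every pair exceeded 0.1, the tumors were treated as sharing only a number. The replicate number as a block left 0 features and 15 lists called.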

Other observations

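All genes in this part except Cdkn2a, Cdkn2b, Krt18, Krt19, Tagln, Lox, Lum, Lyz2, C1qc and Cxcl9 were chosen after their values were seen, and nothing here was tested between groups. The tumors on the low-floor pair of arrays differed widely, with 32.3% of 24171 genes at least 1 log2 unit apart, 3751 higher in Cebpb shRNA tumor 4 and 4059 higher in control tumor 5. Log2 intensities under the receptor level, the 95th percentile of 7.58 on control tumor 5 and 8.23 on Cebpb shRNA tumor 4, are not clearly above background. Some contractile and matrix genes were higher in control tumor 5 while their lists differed less, with 19 of 21 fibroblast genes above the receptor level on each array and median differences (Cebpb shRNA tumor 4 minus control tumor 5) of -0.41 for fibroblast and -0.05 for mesenchymal genes. Acta2, the smooth muscle actin gene, stood at 15.01 in control tumor 5 and 11.63 in Cebpb shRNA tumor 4, Tagln at 13.03 and 7.77, Lox at 14.18 and 9.24 and the collagen gene Col1a1 at 14.89 and 12.63. The matrix genes Lum and Dcn went the other way, at 4.42 and 11.49 in control tumor 5 and 9.40 and 14.06 in Cebpb shRNA tumor 4. The macrophage genes Lyz2 and C1qc stood at 7.43 and 4.86 in control tumor 5 and at 14.54 and 14.24 in Cebpb shRNA tumor 4. The chemokine genes Ccl12 and Cxcl9 stood at 2.53 and 3.97 against 12.75 and 14.07.

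Cdkn2a stood at 11.83 in control tumor 5 and 3.57 in Cebpb shRNA tumor 4, and its neighbour Cdkn2b at 8.81 and 4.87, while 13 of 19 genes of their list, apoptosis and senescence, were higher in Cebpb shRNA tumor 4 (median difference 0.40). Outside the lists, the homeobox gene Hoxc10 stood at 12.59 and 3.91, the imprinted gene Dlk1 at 12.43 and 3.51, the receptor gene Egfr at 9.82 and 3.83 and, within the luminal list, the keratin gene Krt19 at 9.68 and 2.55. Xist, the transcript that silences 1 X chromosome in female cells, stood at 5.11 in control tumor 5 and 10.50 in Cebpb shRNA tumor 4. Epithelial Epcam was low in both at 5.59 and 4.67, while mesenchymal Vim stood at 14.58 and 14.53 and Twist1 at 11.71 and 11.87. Krt18 was lower in control tumor 5, at 7.39 against 10.98.

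Most chromosome Y features were dim on all arrays. The 27 features had a median log2 intensity of 7.61 to 7.80 on the 8 high-floor arrays, beside 7.44 to 7.72 for the random-sequence control, and lay at -1.63 to -1.85 log2 units against the array median. The 1715 features of chromosome X lay at -0.09 to -0.56. On the low-floor pair chromosome Y lay at -3.99 and -4.15 against the array median and chromosome X at -0.48 and -0.62. Kdm5d and Uty, chromosome Y genes with close relatives on X, were bright on the 8 arrays at 11.57 to 12.79 and 10.05 to 10.82. The adipocyte gene Adipoq stood at 10.87 to 12.27 on these arrays against 4.57 and 4.97 on the low-floor pair, but at most 2 of 15 adipocyte genes exceeded the receptor level on any of the 8.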
